A study of Caenorhabditis elegans with 3 samples.

How the data were processed

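ELT-3 was profiled by chromatin immunoprecipitation and sequencing in whole L1 larvae of the C. elegans strain OP75, which carries an unc-119 mutation and the transgene wgIs75. Per the labels, the strain stably expresses ELT-3 with a C-terminal GFP-FLAG tag, the larvae were of pooled sex and the chromatin was sonicated. The 3 libraries form 1 group of 2 biological replicates, and the 2 technical libraries of replicate 1 cannot be told apart because 1 alignment holds both.

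The files used here are 8 peak lists, 4 on the ce10 build and 4 on ce11. On each build there is 1 relaxed list per biological replicate, 1 relaxed list of the pool and 1 list that the authors thresholded on reproducibility. Per the deposited file descriptions, the lists come from the alignments and a control. Reads and control libraries are not analysed here. The aligner, the peak caller and their versions are not given in the sources used here. The deposited signal value of each peak comes from the authors' peak caller, with the control used, on a scale that is not stated. In the thresholded lists the deposited −log10 q of each peak reached its largest value, 3.86, at 3584 of the 4530 peaks on ce11, so peaks were ranked by signal. Summits were taken from the summit offset that the authors deposited with each peak.

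The thresholded ce11 list was the main peak set. Every peak of it was found unchanged in the pooled list, and it was made of the 4530 peaks with the highest signal there. Of these peaks, 4349 overlapped a peak in the relaxed list of each replicate, so not every thresholded peak was found in both. No coordinates were converted between builds, and the ce10 lists were used for counts and overlaps within that build only. Sequences came from the WBcel235 assembly, which is ce11, and gene models from Ensembl release 115, with 19973 protein-coding genes on the 6 nuclear chromosomes. Coordinates are given from 1.

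A summit was assigned to the first of promoter, coding exon, UTR, exon of other genes, intron and intergenic sequence that covered it. Shares were set against 1000 circular shifts of the summits by 10 to 90% of each chromosome's length. WGATAR and 6-base sequences were sought on both strands within 50 bp of the summit and in windows of the same width centred 500 bp to each side, with exact McNemar tests, and for the 6-base sequences the larger of the 2 p-values was adjusted by the Benjamini-Hochberg method. Motif presence and signal were compared with 100000 permutations. Genes with a summit in the promoter of any annotated transcript were set against all other protein-coding genes with two-sided Fisher's exact tests, adjusted over 14 gene lists and separately over 170 gene classes. One member of the junction list, ifa-2, was not matched in the annotation. Exact intervals are Clopper-Pearson at 95% and cover counting error over peaks only, since neighbouring peaks and genes that share a promoter are not independent.

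The designs, gene lists, alternatives and the rule for named genes were fixed before the data were examined. The rule named the genes with a promoter holding 1 of the 10 strongest peaks, the 3 members with the strongest promoter peak of each epidermal list and 2 of each other list, 14 genes given in advance, and the 2 strongest members of the 10 gene classes with the lowest p. Alternatives covered a stricter peak set, the strongest 4530 peaks of each replicate alone, removal of peaks within 20 kb of elt-3 or unc-119, other promoter and motif windows, other backgrounds, other rules for tying peaks to genes and for overlap, and ce10 lists. An intestinal list without the clec family was added after seeing the data.

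The statistics were tested on simulated data. Of 20 sets of 4530 random positions, 0 passed the GATA test. In a set with sites planted at 31.1% of positions, 44.7% had WGATAR against 45.4% expected. Of 100 random sets of 3086 genes, 4 had any gene list past the adjusted threshold. Those genes were drawn independently, so the simulation does not cover neighbours that share a peak. When 50% of the 34 epidermal peptide and osmotic response genes were marked, the list was called in 95 of 100 sets, and another list was called in 9. Computations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and pandas 2.3.3, and plots matplotlib 3.10.9.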

Results

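Binding of ELT-3 was measured by chromatin immunoprecipitation and sequencing in whole C. elegans larvae of the first larval stage, L1. ELT-3 is a GATA-type zinc finger transcription factor known from the epidermis, the tissue that secretes the cuticle. The worms carried a transgene that makes ELT-3 with a GFP-FLAG tag at its C terminus. All 3 libraries belonged to 1 group, with 2 technical libraries of biological replicate 1 and 1 library of biological replicate 2. The files used here hold peaks and no read counts, so the depth of each library is unknown. With 1 group, no comparison between conditions was possible. The comparisons below ask where the peaks lay, which sequences and genes they marked, and how far the replicates shared them. The tests of GATA sites by location and the ranks of 6-base sequences in each replicate were chosen after the first results were seen.

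The thresholded list on the ce11 build held 4530 peaks with a median width of 320 bp, and that on ce10 held 3372. Each was made of the peaks with the highest signal of the pooled list of its build, which held 26508 peaks on ce11. All sequence and gene results refer to ce11. The signal of a peak is the authors' own value, its scale is not stated, and it was used to rank peaks.

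Of the 10 strongest peaks 7 lay in promoters, 5 of them of genes for the translation machinery, and 3 lay in introns. The strongest peak of all, with a signal of 382, lay in an intron on chromosome V, from 9516362 to 9516640, 2322 bp downstream of the nearest transcript start, that of eif-2Bdelta. The next 3 lay in the promoters of rpl-20, rpl-3 and rpl-15, which encode proteins of the large ribosomal subunit. Their signals were 356 for rpl-20 on chromosome IV, from 4749977 to 4750180, 341 for rpl-3 on chromosome III, from 3867479 to 3867693, and 325 for rpl-15 on chromosome IV, from 654816 to 655029. The rpl-20 and rpl-15 peaks also lay in the promoters of the neighbouring genes Y17G9B.5 and K11H12.8. The remaining peaks among the 10 strongest lay at the promoters of iff-2, a translation factor gene that shares its peak with F54C9.14, of cdc-48.1, an AAA ATPase gene, of rps-19 together with hsr-9, and of puf-9, and in introns near epg-9 and D2023.1. The summit at rpl-20 lay nearer the start of Y17G9B.5, and that at rps-19 nearer the start of hsr-9. Of these 10 peaks, 2 had a WGATAR sequence within 50 bp of the summit, where W is A or T and R is A or G. Those were the intron peaks near eif-2Bdelta and D2023.1.

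Promoters held more than their share of the peaks, and coding exons and UTRs held few. Of the 4530 summits, 2587, or 57.1%, lay in a promoter, taken as 1000 bp upstream to 200 bp downstream of a transcript start of a protein-coding gene. After the summits were shifted around each chromosome 1000 times, the promoter share was 25.8% on average, with a central 95% range of 24.5 to 27.1%. Coding exons held 0.817% of summits against 18.8% after shifts, UTRs 0.971% against 2.74%, and introns 14.2% against 27.2%. For these 4 classes the two-sided permutation p was 0.002, the smallest that 1000 shifts can give. Intergenic sequence held 23.7% against 22.8% (two-sided permutation p = 0.22), and exons of other gene types held 3.22% against 2.68% (p = 0.060 in the same permutation test). The median summit lay 548 bp from the nearest transcript start. In replicate 2 alone the intergenic share passed, at 25.1% (permutation p = 0.0080). Exons of other gene types passed in replicate 1 alone, at 4.02% (permutation p = 0.002, the smallest possible), and in replicate 2 alone held less than after shifts, at 2.45%. In replicate 2 alone coding exons held 1.5% and UTRs 1.79%. Chromosome X held 886 summits, or 19.6% (95% exact interval 18.4 to 20.7%), against 17.7% of the bases (two-sided exact binomial p = 0.00099). This excess was not particular to X, which spans 17718942 bp. Chromosome I held 783 summits on 15072434 bp, II 791 on 15279421 bp and III 694 on 13783801 bp, at least as many for their length. Fewer for their length lay on IV, with 643 on 17493829 bp, and on V, with 733 on 20924180 bp. The autosomes were not tested.

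**Figure D1:**
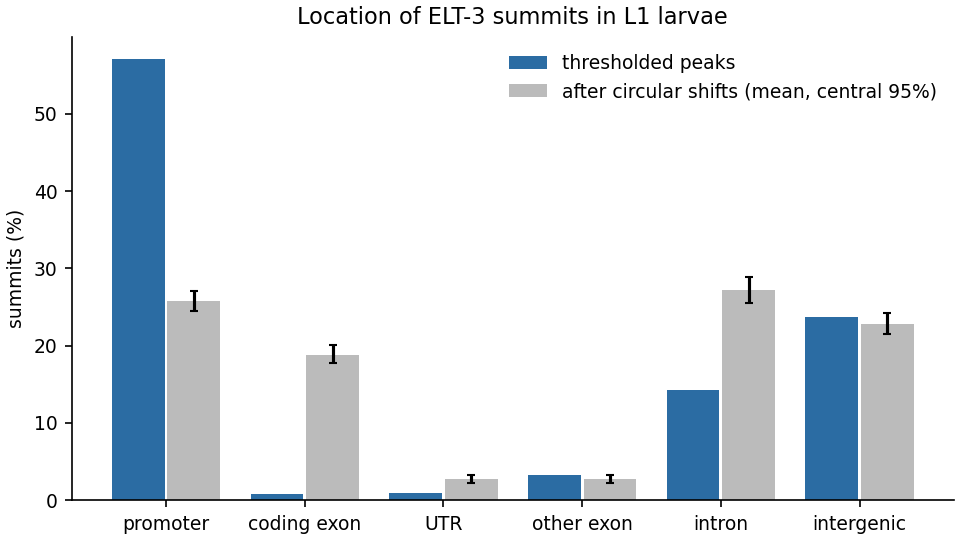
Percent of the 4530 ELT-3 summits in each class of sequence (blue bars) and the mean after 1000 circular shifts of the summits along each chromosome (grey bars, with the central 95% of the shifts as error bars). The promoter bar stands at 57.1% against 25.8% after shifts, and the coding exon bar at 0.817% against 18.8%.

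GATA sites were concentrated under the summits, more so outside promoters than in them. WGATAR lay within 50 bp of 1713 summits, or 37.8% (95% exact interval 36.4 to 39.2%), against 21.3% and 20.6% of windows of the same width 500 bp to the left and right. The exact McNemar p, two-sided, was 7.0e-66 against the left flank and 1.4e-73 against the right. The excess over the mean of the flanks was 16.9 percentage points, and 10.5 in the strongest peaks of replicate 1 alone. Among promoter peaks 31.5% had the site, and among all other peaks 46.3% did (two-sided Fisher's exact p = 3.5e-24). Summits in introns had it in 47.4% of cases, intergenic summits in 47.6%, and the few summits in coding exons and UTRs in 56.8% each, 21 of 37 and 25 of 44. But summits in exons of other gene types had it in 25.3%, below their flanks at 28.8% and 28.1%. Promoter peaks still exceeded promoters without a peak taken at the same distances from the start, of which 20.5% had the site (two-sided Fisher's exact p = 3.1e-19). Of the 4530 peaks, 2817 had no WGATAR within 50 bp of the summit.

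**Figure D2:**
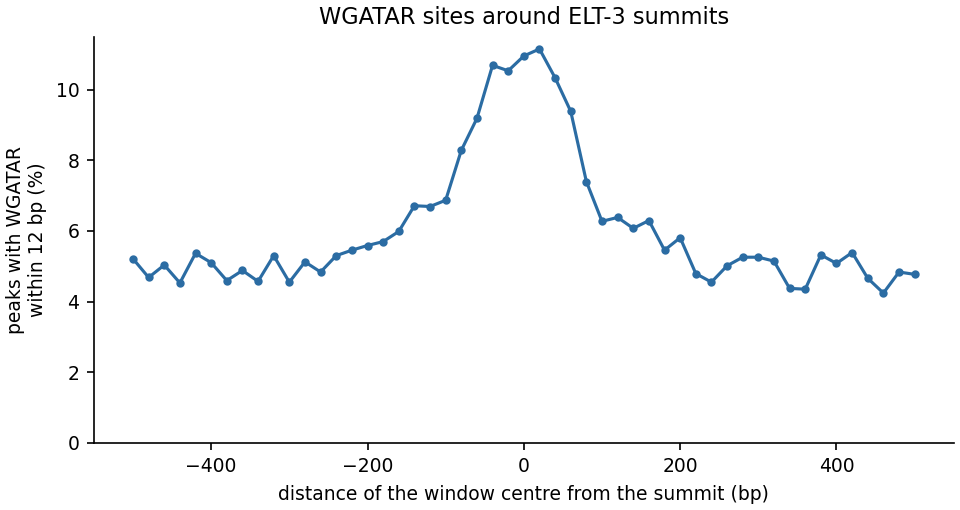
Percent of the 4530 thresholded peaks with WGATAR within 12 bp of a position (y axis) by the distance of that position from the summit in bp (x axis, steps of 20 bp). The share was 10.9% at the summit, 11.1% at 20 bp to the right, 5.21% at 500 bp to the left and 4.77% at 500 bp to the right.

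Against the flanks, other sequences were enriched more strongly than GATA sites. Of 2080 sequences of 6 bases, with reverse complements joined, 673 were more frequent at summits than at both flanks and 487 less frequent, at an adjusted exact McNemar p below 0.05. GAGAGA had the lowest p among those more frequent and was present at 24.6% of summits against 5.52% of flanks. CTGCGT was present at 12% against 1.89%. The first sequence with GATA, GATAAG, ranked 11 among the enriched sequences, at 15.1% against 4.60%, and TGATAA ranked 14, at 22.2% against 10.1%. Many sequences ranked above GATAAG overlap one another. GAGAGA, AGAGAC, GAGACG, AGACGC, GACGCA, ACGCAG and CGCAGA each overlap the next, and ACGCAG is the reverse complement of CTGCGT. WGATAR, in turn, is spread over several 6-base sequences. The ranks therefore do not count separate motifs, and whether the overlapping sequences stand for 1 longer motif was not tested. AAAATT, the sequence with the lowest p of all, was depleted, at 16.6% of summits against 43.8% of flanks. TTAAAA was depleted too, at 9.27% against 28.2%, so base composition may differ between summits and flanks. The ranks of the 6-base sequences are not corrected for that. A shuffled background that keeps pairs of neighbouring bases was run for WGATAR only, which was present at 37.8% of summits against 19.7% of shuffled windows. In the strongest peaks of replicate 1 alone, GATAAG ranked 27 and TGATAA 76, while in those of replicate 2 alone they ranked 2 and 3.

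The share of peaks with WGATAR was slightly higher among peaks with high signal. In 10 bins of 453 peaks by signal it was 43.5% in the bin with the highest signal and 37.5% in the bin with the lowest, but bin 3 from the bottom had the smallest share, 32.5%. Spearman's rho across peaks, which are not independent replicates, was 0.054 (two-sided permutation p = 0.00036). Over the strongest peaks of replicate 1 alone rho was 0.000322, with a permutation p of 0.98, and over those of replicate 2 alone it was 0.154.

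Of 19973 protein-coding genes, 3086, or 15.5%, had a summit in their promoter. Ribosomal protein genes had one far more often than the rest. A promoter peak was present at 68 of 76, or 89.5%, against 15.2% of all other genes (odds ratio 47.5, adjusted p = 2.7e-45 by Fisher's exact test). With each peak tied only to the gene with the nearest transcript start, 39 of 76, or 51.3%, were marked, and the odds ratio fell to 5.25. In the strongest peaks of replicate 2 alone it was 25.4. The strongest, at rpl-20 and rpl-3, are given above. The peak at rps-12, which encodes a protein of the small subunit, had a signal of 278 and no WGATAR within 50 bp.

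Genes for antimicrobial peptides of the epidermis and for the response to osmotic stress were the epidermal list with the clearest excess. Of its 34 members 16, or 47.1%, had a promoter peak, against 15.4% of other genes (odds ratio 4.88, adjusted p = 4.8e-05 by Fisher's exact test). The strongest peak, with a signal of 176 and 3 WGATAR sites within 50 bp, had its summit at 3980038 on chromosome V in the promoters of nlp-31 and nlp-34, which are both genes for neuropeptide-like proteins. The STAT-like gene sta-2 had a peak with a signal of 124 and no WGATAR within 50 bp. nlp-29, a gene for an epidermal antimicrobial peptide, had a promoter peak with a signal of 65.3, and gpdh-1, a glycerol-3-phosphate dehydrogenase gene used in the osmotic response, had one with a signal of 47.6. The gpdh-1 peak overlapped none in the list of replicate 2. The call of this list was lost in the 2265 thresholded peaks with the highest signal, with 6 members marked and an adjusted p of 0.21 by Fisher's exact test. It was also lost in the strongest peaks of replicate 1 alone, with 11 members marked and an adjusted p of 0.054 by the same exact test.

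Genes for epidermal junctions and attachment had a promoter peak in 6 of 15 cases, or 40%, and missed the threshold (odds ratio 3.65, adjusted p = 0.054 by Fisher's exact test). The spectraplakin gene vab-10 had a signal of 88.4, let-805, which encodes a transmembrane protein of the epidermal attachments to muscle, 74.4, and mup-4 73.1. In the strongest peaks of replicate 2 alone the list passed, with an adjusted p of 0.035 by the same exact test. It also passed when each peak was tied to the gene with the nearest transcript start, with an odds ratio of 5.65 and an adjusted exact p of 0.0038.

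Cuticle collagen genes were marked about as often as other genes. A promoter peak lay at 28 of 174, or 16.1% (odds ratio 1.05, adjusted p = 0.97 by Fisher's exact test). Against circular shifts, which give every list a lower expected count, collagens passed, with 28 marked against 9.08 after shifts (adjusted permutation p = 0.0070). The strongest were at dpy-10, with a signal of 182 and no WGATAR within 50 bp, at col-62, with a signal of 130 and 2 such sites, and at col-38, with a signal of 126. The col-38 peak also lay in the promoter of rpl-5. No promoter peak was found at the collagen genes dpy-7 and rol-6, and the nearest summit to rol-6 lay upstream of its promoter, at 8731162 on chromosome II, with a signal of 111.

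The other epidermal lists missed the threshold by the same exact test. Hedgehog-related and patched-related genes had a promoter peak in 7 of 85 cases (odds ratio 0.490, adjusted exact p = 0.16), among them grl-11, ptr-6 and hog-1 with signals of 74.1, 68.4 and 64.1. Molting and apical matrix genes had one in 7 of 61 cases (odds ratio 0.709, adjusted exact p = 0.61), with dpy-6, dpy-31 and lpr-3 at 102, 93.5 and 65.2. In replicate 2 alone 3 of 61 had one (odds ratio 0.315, adjusted exact p = 0.095). The lpr-3 peak ranked 1996 in the pooled list and 21077 of the 27330 peaks of replicate 2. Epidermal transcription factors had one in 3 of 14 cases (odds ratio 1.49, adjusted exact p = 0.61). These were elt-3 itself, with a signal of 180, and the nuclear receptor genes nhr-25 and nhr-23, with 54.2 and 46.0. With each peak tied to the nearest transcript start this list passed, with 6 of 14 marked, an odds ratio of 3.71 and an adjusted exact p of 0.047. That setting was not run without the peaks near elt-3, a member of the list. Under the promoter rule, leaving out peaks within 20 kb of elt-3 or unc-119 gave an odds ratio of 0.913. No promoter peak was found at elt-1, egl-18, elt-6 or lin-26, although egl-18 had a summit in an intron 2145 bp downstream of its start with 2 WGATAR sites within 50 bp. Of 11 GATA factor genes, 1 had a promoter peak, elt-3 (odds ratio 0.547, adjusted exact p = 1). The intestinal GATA factor genes elt-2 and elt-7 had none.

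Chemoreceptor genes and the intestinal list were marked less often than other genes. Of 851 chemoreceptor genes, 14, or 1.65%, had a promoter peak, against 16.1% of the rest (odds ratio 0.0874, adjusted p = 4.4e-43 by Fisher's exact test). The odds ratio was 0.0319 with promoters of 500 bp upstream and 100 bp downstream and 0.151 with neighbouring members counted once. The strongest were at srh-17, with a signal of 151, and srh-2, with 131. Of 262 members of the intestinal list, 4, or 1.53%, had a promoter peak (odds ratio 0.0837, adjusted p = 1.0e-13 by Fisher's exact test). The odds ratio of this list was 0.0416 in the 2265 thresholded peaks with the highest signal and 0.153 with each peak tied to the nearest transcript start. After circular shifts 13.6 members were marked on average. That list was made up mostly of 240 genes of the clec family of C-type lectins, to which all 4 marked members belonged, clec-146 and clec-102 with the highest signals of 63.8 and 59.9. The 22 other members had no promoter peak, and without the clec genes the list missed the threshold, at an adjusted p of 0.11 by Fisher's exact test, a test chosen after seeing the data.

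The lists for other tissues did not pass the threshold. Body-wall muscle genes had a promoter peak in 0 of 18 cases (adjusted p = 0.19 by Fisher's exact test) and pharynx genes in 0 of 16 (adjusted exact p = 0.25). Germline genes had one in 1 of 24 cases, at the RNA helicase gene cgh-1 with a signal of 71.2 (adjusted exact p = 0.25). Neuronal genes had one in 3 of 21 cases (adjusted exact p = 1), the strongest at the synaptobrevin gene snb-1, with 91.9, and at ric-19, with 55.5.

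**Figure D3:**
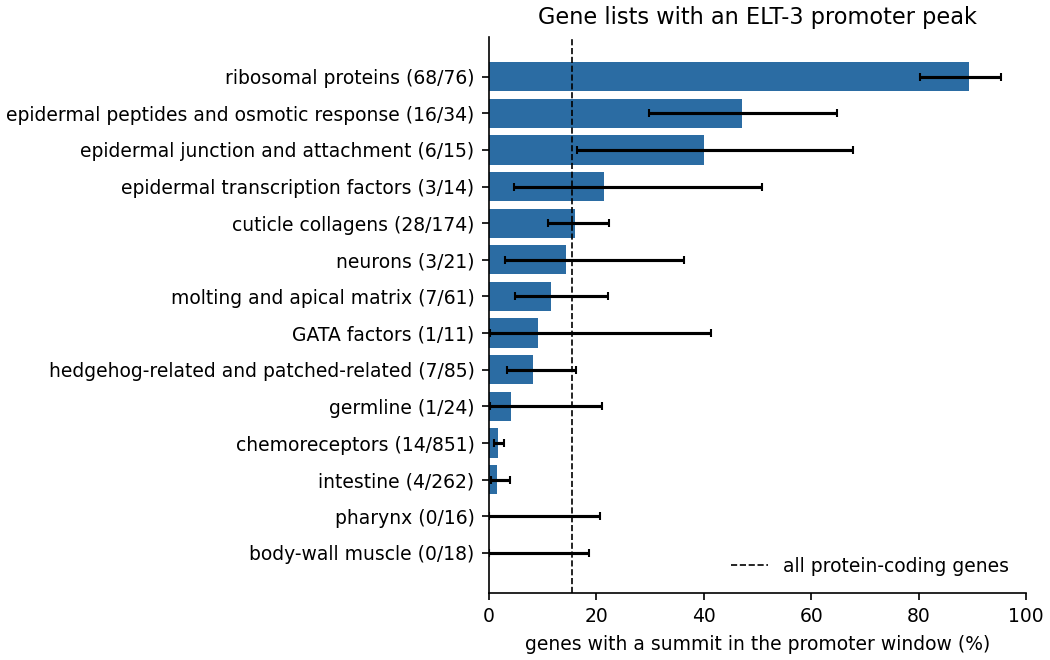
Percent of the members of each of 14 gene lists with an ELT-3 summit in the promoter (bars, with the marked members and the list size beside each name, and 95% exact intervals as error bars). The dashed line marks the 15.5% of all protein-coding genes. Ribosomal protein genes stand at 89.5% and epidermal peptide and osmotic response genes at 47.1%, while chemoreceptor genes stand at 1.65%.

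Over all 170 classes of genes with a shared symbol and 10 or more members, 15 had promoter peaks more often than other genes and 24 less often, at an adjusted Fisher's exact p below 0.05. The classes with the lowest p that were marked more often were rpl with 39 of 45, rps with 29 of 31, alh with 10 of 13 and rpn with 9 of 13. The alh class holds aldehyde dehydrogenase genes, with alh-1 and alh-9 the strongest at signals of 146 and 130, and rpn holds genes of the proteasome's regulatory particle, with rpn-3 and rpn-9 at 132 and 116. The classes marked less often with the lowest p were clec with 4 of 240, str with 3 of 193, srh with 7 of 220, srx with 0 of 101, srw with 2 of 109 and fbxa with 7 of 170. All but clec and fbxa are chemoreceptor classes. Their strongest members were str-176 with 107 and str-7 with 75.2, srw-67 with 49.0 and srw-145 with 45.2, and fbxa-90 with 133 and fbxa-38 with 114. The dpy class, chosen after its values were seen, had 10 of 25 members marked (adjusted p = 0.016 by Fisher's exact test). Several other classes marked more often had a lower p than dpy. They were npp with 12 of 26, lin with 17 of 45, rpb with 7 of 11, dnj with 12 of 29, hsp with 10 of 22 and rbm with 7 of 13.

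The replicates shared most of their strong peaks, and their signals correlated weakly over the thresholded peaks. Of the 4530 strongest peaks of replicate 1, 2821, or 62.3% (95% exact interval 60.8 to 63.7%), overlapped one of the 4530 strongest of replicate 2 by 1 bp or more. After 100 circular shifts the share was 2.67% on average and at most 3.44% (one-sided permutation p = 0.0099, the smallest that 100 shifts can give). Of the thresholded peaks, 4349, or 96.0%, overlapped a peak in the full list of each replicate. Over these peaks Pearson's r of the log10 signals was 0.246 (95% bootstrap interval 0.218 to 0.274) and Spearman's rho was 0.261. Over the 11207 peaks of the relaxed pooled list found in both replicates, a set chosen after the first results were seen, r was 0.637 and rho 0.612. These are correlations across peaks, which are not independent replicates.

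The elt-3 gene lay in a region dense with peaks. A 40 kb window centred on it held 29 peaks of the pooled list, against a median of 10 over 5004 windows, at percentile 99.4. It held 38 peaks of replicate 1, 27 of replicate 2 and 10 thresholded peaks. Of the thresholded peaks, 5 had their summit inside elt-3, which spans 13934874 to 13941216 on chromosome X. The strongest of these lay in an intron from 13937504 to 13937726, with a signal of 220 and 3 WGATAR sites within 50 bp. The window centred on unc-119, the gene mutated in this strain's background, held 12 pooled peaks, at percentile 62.8, and no thresholded peak lay in the unc-119 promoter. In 100 kb windows the percentile of elt-3 was 85.7.

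**Figure D4:**
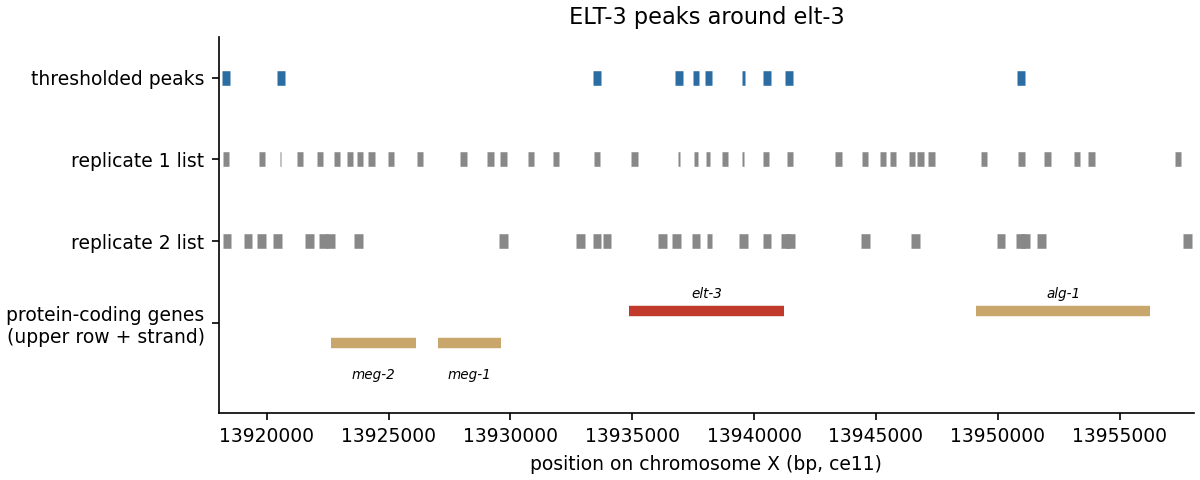
Map of the 40 kb around elt-3 on chromosome X (x axis, position in bp on ce11) with the 10 thresholded peaks (blue), the peaks of each replicate's own list (grey) and protein-coding genes (red for elt-3, tan for others). The region holds 38 peaks of replicate 1 and 27 of replicate 2.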

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

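Of 32 results, the promoter excess, the share on X, the GATA excess, the replicate overlap and the calls for ribosomal proteins and chemoreceptors kept their direction and call under each alternative run for them, but not their size. The ribosomal odds ratio of 47.5 fell to 5.25 with the nearest gene, that of chemoreceptors, 0.0874, ran from 0.0319 with short promoters to 0.151 with neighbours counted once, and the GATA excess of 16.9 points was 10.5 to 19.6 with 1 replicate. The promoter excess ranged from 1.56 to 3.31 times the shifted share. Except where a reason is given, the cause was not tested. With 1 replicate at a time, the share in exons of other genes ran from 2.45 to 4.02%, the intergenic share from 22.9 to 25.1%, the number of enriched 6-base sequences from 439 to 740, rho of motif and signal from 0.000322 to 0.154, the odds ratio of the junction list from 3.56 to 4.08, that of the epidermal peptide list from 2.56 to 3.34, of molting genes from 0.315 to 0.805, of ribosomal proteins from 25.4 to 36, and the percentile of unc-119 from 69.0 to 84.4. The overlap, the correlation and the thresholded list have no value with 1 replicate. In the 2265 strongest peaks the share in exons of other genes was 2.56%, below its shifted share, 14 gene classes passed against 39 in the full list, and odds ratios were 0.887 for collagens, 0.846 for epidermal factors, 1.1 for GATA factors and 2.36 for epidermal peptides. Promoters of 500 and 100 bp raised the share in other exons to 4.0% and intergenic sequence to 30.1%, and promoters of 2000 and 500 bp left 15% intergenic, since they take up or release that sequence. With the nearest gene, odds ratios were 0.987 for collagens, 1.62 for hedgehog-related genes, 1.61 for molting genes, 3.71 for epidermal factors, 5.65 for junctions, 1.16 for neurons and 1.1 for GATA factors. With circular shifts, observed over shifted counts were 3.08, 1.52, 1.90, 2.90, 2.10 and 1.43 for collagens, hedgehog-related genes, molting genes, junctions, neurons and GATA factors. Shifts move summits off promoters, leaving 1204 genes with a peak on average against 3086, so this background is lower for every list. Collagens and junctions passed against it. Counting neighbouring members once, with neighbours of 1 class joined in the background, gave 0.998 for collagens. Without peaks near elt-3 or unc-119 epidermal factors had 0.913, as elt-3 itself was removed. The intestinal list without clec genes, chosen after seeing the data, had an odds ratio of 0. The replicate correlation was 0.165 on ce10 and 0.276 with summits matched within 100 bp. The percentile of elt-3 was 85.7 in 100 kb windows, and that of unc-119 was 78.4 in 20 kb and 34 in 100 kb windows. The number of gene lists past the threshold ran from 3 to 6 over the alternatives, against 4. Depth is unknown, so a gene without a peak cannot be told from one missed by the caller.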

Other observations

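The tests of ribosomal protein promoters and of the elt-3 region were chosen after related results were seen. The tests of the order of peaks in the replicates, of GATA sites at epidermal genes and of tRNA genes were written before their results, and all other tests here were chosen after the data were seen.

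Genes for tRNAs and snoRNAs held summits more often than after circular shifts. A summit lay within 200 bp of 86 of 612 tRNA genes, or 14.1%, against 2.21% after 1000 circular shifts, and of 64 of 346 snoRNA genes, or 18.5%, against 2.41%. For snRNA genes it was 7.75% against 2.11%, and for lincRNA genes 15.5% against 6.69%. Pseudogenes and piRNA genes held fewer than after shifts, at 0.799% against 7.27% and 0.482% against 1.67%. In these 6 classes the two-sided permutation p was 0.002, the smallest possible, and 0.0023 after adjustment over 7 classes. For miRNA genes the share was 2.30% against 2.29% (permutation p = 1). Shifts also lowered the number of protein-coding genes with a promoter peak, from 3086 to 1204 on average, so an excess over shifts of that size, as for lincRNA genes, does not set a class apart. Summits in exons of genes that do not code for protein were also the class in which WGATAR was not more frequent than at the flanks, at 25.3% against 28.8% and 28.1% (exact McNemar p = 0.59 and 0.68).

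Among genes with a promoter peak, members of the epidermal lists, as 1 set, had a GATA site under it more often than others. Of 67 members of the epidermal lists, 36, or 53.7%, had WGATAR within 50 bp of their strongest promoter summit, against 26.5% of other genes (odds ratio 3.22, two-sided Fisher's exact p = 4.3e-06, adjusted p = 1.7e-05 over 8 comparisons). Collagen genes had it in 16 of 28 cases, or 57.1%, hedgehog-related and patched-related genes in 5 of 7, or 71.4%, epidermal peptide and osmotic response genes in 9 of 16, or 56.2%, and chemoreceptor genes, which are not epidermal, in 9 of 14, or 64.3%. Junction genes, at 3 of 6, and molting and apical matrix genes, at 2 of 7, missed the threshold (adjusted Fisher's exact p = 0.40 and 1). When only the 1713 peaks with WGATAR were used, collagens were marked more often than other genes, at 9.20% against 4.44% (odds ratio 2.18, adjusted p = 0.029 by Fisher's exact test), and epidermal peptide and osmotic response genes at 26.5% (odds ratio 7.74, adjusted p = 9.3e-05 by the same exact test), while hedgehog-related and patched-related genes missed the threshold (odds ratio 1.33, adjusted exact p = 0.76). These counts take members that share a peak separately, as col-117 with col-3, col-159 with col-160, and nlp-31 with nlp-34. Counting neighbouring members once was not run for peaks with WGATAR, so whether the collagen call would hold then is unknown. Chemoreceptor genes were marked less often by the peaks with WGATAR, at 1.06% against 4.63% (odds ratio 0.220, adjusted exact p = 1.9e-07). In the 2817 peaks without it collagens had an odds ratio of 0.566 (adjusted exact p = 0.16), hedgehog-related and patched-related genes 0.184 (adjusted exact p = 0.012), and epidermal peptide and osmotic response genes 1.99 (adjusted exact p = 0.25). These data are consistent with binding of epidermal genes through GATA sites, as a hypothesis that rests mainly on the collagen and peptide lists, since only these 2 epidermal lists passed the threshold for peaks with WGATAR. The few chemoreceptor genes with a promoter peak also had GATA sites under it.

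Ribosomal protein promoters were marked at 68 of 76 genes under the promoter rule and had almost no GATA site under the summits. Of their 67 peaks, 2.99% had WGATAR within 50 bp of the summit, below 32.2% of the peaks at other promoters (two-sided Fisher's exact p = 4.9e-09) and not above their own flanks, at 16.4% on the left and 7.46% on the right (exact McNemar p = 0.022 and 0.45). This argues against GATA sites under the summits as the way these promoters were marked. Signal at promoters of active genes that needs no GATA site may account for them. GAGAGA or CTGCGT was present at 29.9% of these peaks against 32.2% at other promoters (two-sided Fisher's exact p = 0.79). These sequences were picked from those enriched at the same summits and were about as frequent at peaks outside promoters, at 31.9%. They do not mark promoters, so that test cannot decide the question and left it open. No immunoprecipitation without the tagged protein is analysed here. No other explanation was tested.

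The low correlation of signal between replicates has explanations that do not exclude each other. Over the 11207 peaks of the relaxed pooled list found in both replicates Pearson's r was 0.637, against 0.246 over the thresholded peaks, which is consistent with the selection of peaks on their pooled signal lowering r. The replicates also differed in kind. The median log2 ratio of replicate 1 to replicate 2 at peaks with WGATAR, minus that at peaks without, was -0.59 (95% bootstrap interval -0.67 to -0.51, two-sided permutation p = 1e-04, the smallest that 10000 permutations can give), a difference that a constant factor between the lists does not change. That interval and that permutation p cover the spread over peaks, which are not independent, and not the spread between replicates. Of the 4530 strongest peaks of each replicate, 31.8% had WGATAR in replicate 1 and 40.4% in replicate 2. The same difference of medians was 0.36 for promoter peaks, 0.49 for ribosomal protein promoter peaks, 0.26 for peaks with GAGAGA or CTGCGT and -0.038 for peaks on X. WGATAR was rarer in promoter peaks, at 31.5% against 46.3% elsewhere, so these values do not tell the site and the location apart. The design names no biological difference between the replicates, so no biological explanation was tested. Replicate 1 held 2 technical libraries and replicate 2 held 1, and their relaxed ce11 lists had median peak widths of 260 and 364 bp. Whether these technical differences bear on the signals was not tested either.

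Extra copies of the elt-3 region in the transgene may raise the number of peaks called there. In the 40 kb window peaks without WGATAR stood at percentile 99.8 in replicate 1 and 97.8 in replicate 2. They made up 28 of 38 and 18 of 27 of the peaks there, so these percentiles largely restate the density of the region and do not decide for or against extra copies. Peaks with WGATAR stood at 99.3 and 98.5, and binding in this region stays open as well. The copies of the transgene and its boundaries are not given in the sources used here.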
